A study of Mus musculus with 12 samples.

How the data were processed

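Lung total RNA of mice was measured on Agilent arrays, 1 array per sample, in 4 groups of 3 biological replicates. The groups were dams and prenatal offspring after gestation in diluted cigarette smoke or in filtered air. Group and replicate number came from the sample titles, and the slide of each array from the scan names in the descriptions. The deposited table held intensity values for 41267 probes on 12 arrays, of which 93 were control probes, and it had 0 missing values. These deposited intensity values were linear and single-channel. Their 75th percentiles differed between arrays, so they were read as not scaled between arrays. Per the labels' protocols the lung RNA carried Cy5 and a universal mouse reference carried Cy3, whereas the scan names carried a 1-colour protocol code. Which channel the values hold, and what background subtraction preceded them, is not given in the sources used here. If they were the reference channel, differences between groups would not be differences in lung RNA. A universal reference would read alike on every array apart from technical differences. The offspring groups did not overlap for 58.4% of probes, where chance gives 10%. Brightness and the spike-in ratio stay open as causes of that separation, so it does not decide the channel. At 46 probes 2 or more arrays were bright and the others more than 4-fold dimmer. These 46 probes argue against the reference channel, although the labels do not settle which channel was used.

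The design fixed before the data were examined had assumed values on a log scale and 1 row per gene. Because the values were linear, each array was instead divided by its 75th percentile over the 41174 probes that are not controls, floored, and converted to log2. The floor was the highest scaled background of any array, where the background was the 95th percentile of 50 control probes without a target. It lay at 1.16% of the 75th percentile, or -6.42 on the log2 scale. Probes above the floor on at least 3 arrays were kept, which left 28185 tested and 12989 left out. Every log2 difference is on this floored scale, which understates changes of dim probes. The number of arrays limits the precision.

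Differences were tested per probe with limma 3.58.1 in R 4.3.3, by lmFit and eBayes with default settings and 1 mean per group over all 12 arrays, which left 8 residual degrees of freedom. All tests were two-sided, and a probe was called at a Benjamini-Hochberg adjusted p under 0.05. The contrasts were smoke against air in dams, smoke against air in offspring, the difference of these effects, and offspring against dams in air. Offspring against dams in smoke was added after the data had been seen. The smoke effects of dams and offspring were correlated across probes, with an exact permutation test over 400 reassignments of the labels within each stage. Other computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

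The steps were tested on simulated data with 200 probes changed among 28185, drawn with the fitted spread. For smoke against air in dams the fit called 78% of the probes changed by 1 log2 unit and 96% of those changed by 2, with 10 false calls. For offspring it called 67% and 99%, with 4 false calls, and for offspring against dams in air 82% and 98%, with 9 false calls. The simulated noise was independent between probes, had 1 spread per probe for all groups and held no array apart from its group. In the data the median SD per probe ran from 0.122 in offspring smoke to 0.204 in offspring air on the log2 scale. These shares may therefore overstate what could be called in the data.

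None of the probe identifiers matched the gene table used here (0 matches), so probes are given by identifier and no gene is named. The 41 gene lists and the cell type markers fixed in advance were therefore not tested. The rule fixed for named genes was kept in its order. It took the largest differences among called probes whose groups did not overlap, or the smallest p for the difference of effects and where fewer than 10 probes were called in all. At most 2 higher and 2 lower probes per comparison are printed, and only probes above the floor on every array compared, a restriction added after the data had been seen.

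The closest pair of arrays, dam air replicates 1 and 3, correlated at r = 0.997 across probes and shared 0 identical values, so all arrays were counted. Slides were tested as a batch. Each of the 3 slides held several groups, but none held all 4. With slide added to the groups, 0 probes passed the threshold for slide in limma. An unadjusted p under 0.05 was seen at 2044 probes, where chance gives 1409. Slide and group overlap in part, so this test may miss a difference between slides. The consensus correlation within slides was 0.0337. Alternatives fixed in advance were the replicate number and the slide as blocks, median centring, quantile normalization, a fit of the compared groups alone, a plain t-test, a trended robust spread, array weights, removal of the dimmer probes and removal of each array. Alternatives chosen after the data had been seen were no floor, no scaling, scaling to 6 spike-in probes, a spike-in covariate, and removal of 2 arrays together.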

Results

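The series asked how lung gene expression of mouse dams and of their prenatal offspring responds to tobacco smoke during gestation. Dams breathed mainstream smoke of 3R4F cigarettes, a filtered research cigarette made to a fixed specification, diluted 1 part in 50 with filtered air, or breathed filtered air. Exposure lasted 4 h per day on 5 days per week over 18 days. Per the labels all mice were female, of a strain written B6C6F1. Each of the 4 groups had 3 arrays, described in the labels as biological replicates. The labels do not say whether offspring shared a litter, so p-values measure the spread between these samples.

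The median intensity of replicates 1, 2 and 3 was 69.3, 90.3 and 77.8 in dam smoke and 75.7, 76.9 and 74.8 in dam air. In the same order it was 67.2, 36.4 and 42.5 in offspring smoke and 64.3, 71.6 and 101.6 in offspring air. The 75th percentile was 491 and 549 in offspring smoke replicates 2 and 3 and lay between 839 and 1164 on the other 10 arrays, including 917 in offspring smoke replicate 1. Between 64.6% and 67.3% of the probes were above the background floor on each array. Across 28185 probes, the first principal component held 54.5% of the variance and the second 13.5%. On the first component the offspring smoke arrays scored 73.3, 83.5 and 77.6. Dam smoke replicate 3 scored 12.2 and offspring air replicate 2 scored -11.5, away from their groups, and the remaining 7 arrays scored between -43.3 and -28.0.

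**Figure D1:**
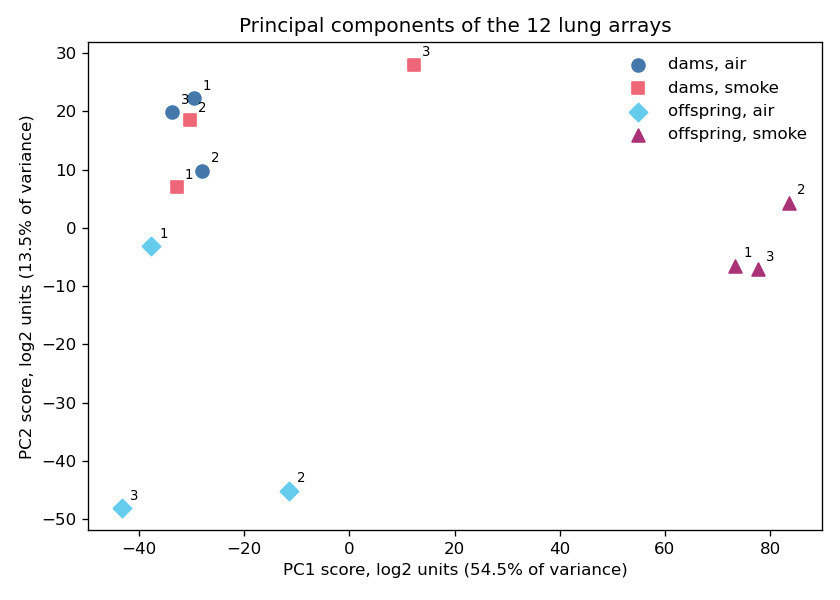
Scores of the 12 arrays on the first and second principal components of the log2 values, with the percent of variance on each axis. Symbols mark the groups and numbers the replicates; the offspring smoke arrays lie at 73.3 to 83.5 on the first component, and dam smoke replicate 3 lies at 12.2.

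The arrays carry E1A control probes for spike-in RNA, and 6 of them were set against the lung RNA signal; the amount added to each sample is not given in the sources used here. The spike-in signal divided by the 75th percentile was 3.74 ± 0.423 (SD, n = 3) in offspring smoke and 2.38 ± 0.819 (SD, n = 3) in offspring air. It was 2.02 ± 0.653 (SD, n = 3) in dam smoke and 1.70 ± 0.140 (SD, n = 3) in dam air. The exact permutation p for smoke against air was 0.1 in offspring, the smallest that 3 arrays against 3 allow, and 0.7 in dams (two-sided, n = 3). Dam smoke replicate 3, at 2.76, and offspring air replicate 2, at 3.23, had the highest ratios of their groups.

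**Figure D2:**
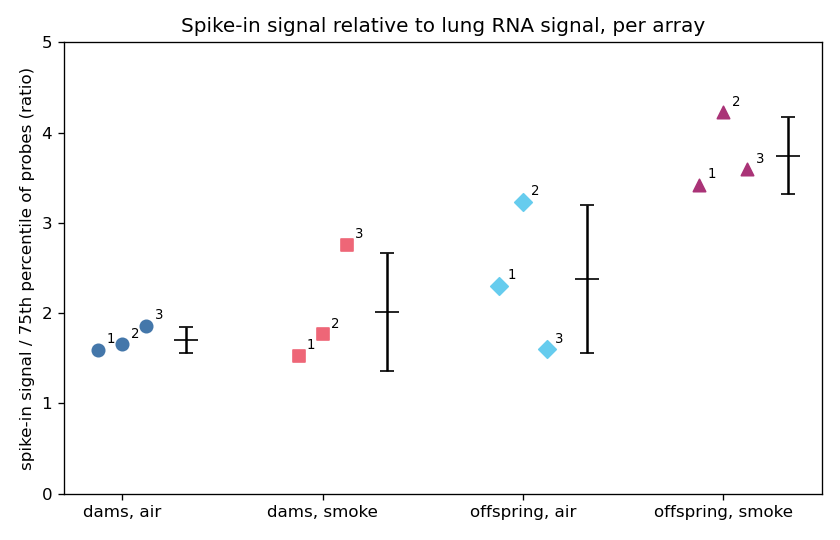
Ratio of the spike-in signal to the 75th percentile of the probes, per array, with the replicate number beside each point. The bars give the mean and SD of the 3 arrays of each group; the offspring smoke arrays lie at 3.42, 4.22 and 3.59.

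The first comparison asked whether smoke changed the lungs of the dams. No probe was called, and the values of the 4 named probes, chosen for small p, did not overlap between the dam groups. Probe A_51_P461067 measured 94.0 ± 50.5% of the 75th percentile in dam smoke and 10.5 ± 3.29% in dam air (SD, n = 3 each). Its log2 difference was 3.03 with a standard error of 0.43 and an adjusted p of 0.156 in limma. In the offspring the same probe measured 7.23 ± 0.262% in smoke and 4.38 ± 1.76% in air (SD, n = 3 each). Probe A_51_P115601 measured 22.7 ± 5.20% in dam smoke and 8.12 ± 1.5% in dam air, with an adjusted p of 0.151 in limma. Among lower values, A_51_P137604 measured 9.69 ± 1.06% in dam smoke and 16.7 ± 1.07% in dam air, and A_52_P639043 measured 1.28 ± 0.102% and 2.22 ± 0.235% (SD, n = 3 each), with adjusted p of 0.156 and 0.163 in limma. Limma called 0 of 28185 probes and gave 1166 an unadjusted p under 0.05, where chance gives 1409. The plain test of equal variance also called 0. The groups did not overlap for 11.4% of probes, where chance gives 10%. On slide 3, the only slide with both dam groups, the difference of its 1 smoke and 1 air array correlated at r = 0.00480 across probes with that of the other dam arrays. That smoke array is dam smoke replicate 3, which lay apart from its group, and the other dam smoke arrays are all on slide 1 and the other dam air arrays all on slide 2. Without dam smoke replicate 2 limma called 7 probes, without dam smoke replicate 3 it called 2, and without offspring air replicate 2 it called 1. Array weights gave 1036 calls. Probe A_51_P461067 was called in 4 of its 26 alternative settings, with adjusted p of 0.00397 without dam smoke replicate 2, 0.00475 with array weights, 9.7e-05 without scaling and 0.0110 with spike-in scaling, and a log2 difference of 2.28 to 3.58 in these. A_51_P115601 was called in 3 settings (without dam smoke replicate 2, with array weights and without scaling), and the lower probes with array weights alone.

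Lungs of smoke-exposed offspring differed from those of air offspring at 15000 of 28185 probes, 53.2% of those tested. Of these, 7919 were higher and 7081 lower, with a median absolute log2 difference of 0.66. More than 2-fold differences were mostly decreases, with 698 probes higher and 2507 lower, and beyond 4-fold 41 were higher and 245 lower. The groups did not overlap for 58.4% of probes, where chance gives 10%. Probe A_51_P508781 measured 4.92 ± 0.272% of the 75th percentile in offspring smoke and 53.9 ± 9.37% in offspring air (SD, n = 3 each), a log2 difference of -3.44 with a standard error of 0.14 and an adjusted p of 1.14e-06 in limma. Dam smoke and dam air arrays held this probe at 50.6 ± 5.42% and 52.6 ± 2.84% (SD, n = 3 each). It is among the 46 probes, described under other observations, at which the arrays fell into a bright and a dark set. Inherited differences, which may leave such a pattern, were not tested. Probe A_51_P515137 fell by 3.39 on the log2 scale, from 19.4 ± 5.87% to 1.89 ± 0.692% (SD, n = 3 each), with an adjusted p of 1.76e-04 in limma.

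The probes with the largest increases had a wide spread within offspring air. Probe A_52_P570717 measured 284 ± 43.1% in offspring smoke and 45.3 ± 65.9% in offspring air (SD, n = 3 each), where the 3 air arrays read 11.7%, 121% and 2.89%. Its log2 difference was 4.14 with a standard error of 0.96, and dam air held it at 160 ± 8.11% (SD, n = 3). Probe A_52_P152133 gave 488 ± 57.2% in offspring smoke, against 23.1%, 209% and 6.47% on the air arrays and 324 ± 23.1% in dam air (SD, n = 3). Both probes are also among the 46 with a bright and a dark set. Both calls were lost with the plain test (adjusted p 0.116 and 0.110) and with the spike-in covariate, where the log2 differences were 1.89 and 1.84 (adjusted p 0.113 and 0.0994). For A_52_P570717 the log2 difference was 3.91, 5.59 and 2.90 without offspring air replicates 1, 2 and 3, and for A_52_P152133 it was 3.72, 5.31 and 2.81. Calls were more frequent among bright probes, with 2515 among the 7047 dimmest probes and 4587 among the 7046 brightest. Their direction also changed with brightness. Among the dimmest 877 were higher and 1638 lower in offspring smoke, and among the brightest 3008 were higher and 1579 lower. The median log2 difference was -0.092 in the dimmest and 0.222 in the brightest probes, and the cause of this trend was not tested.

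The share of higher probes among the calls depended on the scaling and on how dim probes were treated. It was 52.8% with the 75th percentile, 63.4% with median centring, 1.7% without scaling and 1.1% with scaling to the spike-ins. The last 3 settings moved the median log2 difference of all probes from 0.05 to 0.18, -0.49 and -0.58. With the 75th percentile the higher share was 62.7% without the floor and its filter, and 61.0% with the dimmer probes left out. Slide as a block left 12154 calls. On slide 1, the only slide with both offspring groups, the difference of its 1 smoke and 1 air array correlated across probes with that of the other offspring arrays at r = 0.721, and 79.3% of probes had the same sign. Probes are not independent replicates. The spike-in ratio, which also moved with the groups, left 6982 calls as a covariate, and the plain test of equal variance gave 9084.

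**Figure D3:**
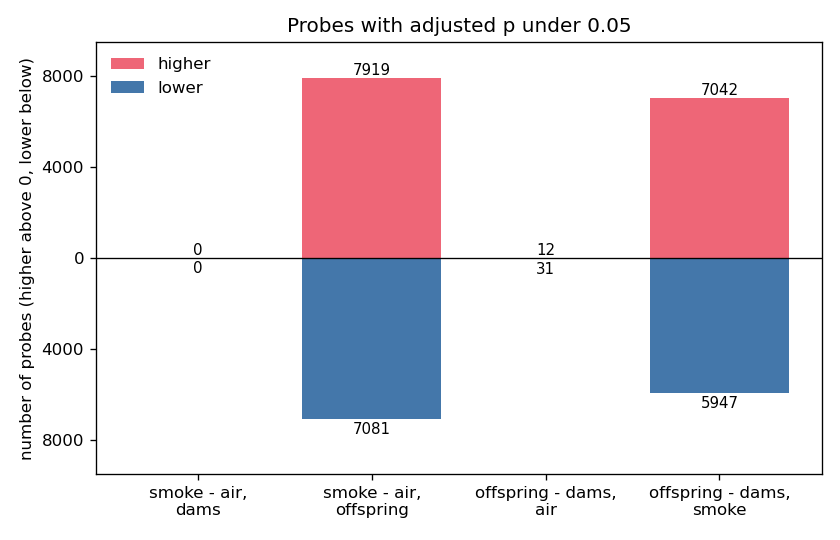
Number of probes with an adjusted p under 0.05 in limma for 4 contrasts, higher above the zero line and lower below it. Smoke against air gave 7919 higher and 7081 lower probes in offspring and 0 in dams; the split by direction depends on the scaling, with 1.1% higher in offspring under spike-in scaling.

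Whether offspring and dams responded differently was tested as the difference of the smoke effects. It passed the threshold at 6687 probes, 3085 with a higher and 3602 with a lower effect in offspring. Probe A_51_P508781, 10.8-fold lower in smoke-exposed than in air offspring, had the smallest p, with an adjusted p of 5.68e-05 in limma. Probe A_52_P679101 measured 195 ± 6.92% in offspring smoke and 1373 ± 238% in offspring air, and 724 ± 120% and 791 ± 123% in dam smoke and dam air (SD, n = 3 each). Probes A_51_P137604 and A_51_P196663 moved the other way, with differences of 1.82 and 1.58 on the log2 scale. A_51_P196663 measured 124 ± 3.26% in offspring smoke against 63.3 ± 7.15% in offspring air, and 66.8 ± 3.37% in dam smoke against 101.4 ± 7.30% in dam air (SD, n = 3 each). With slide as a fixed block 42 probes were called and with slide as a random block 6164. With spike-in scaling 10 were called, where A_51_P137604 and A_51_P196663 had adjusted p of 0.136 and 0.186; the latter was not called without scaling either (adjusted p 0.102). The higher share was 46.1%, against 57.0% with median centring, 0.9% without scaling and 10% with spike-in scaling. Leaving out dam smoke replicates 1 or 2 gave 3236 or 3074 calls, dam air replicates 1 or 3 gave 3246 or 4347, offspring smoke replicates 2 or 3 gave 4151 or 3918, and offspring air replicate 3 gave 4353.

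The smoke effects of dams and offspring correlated across probes at Pearson r = 0.328 and Spearman rho = 0.390, with the same sign at 64.8% of probes. The exact permutation p over 400 reassignments was 0.42 for r and 0.37 for rho. Without dam smoke replicate 3 r was -0.0557, so the relation rested on that array. With slide means removed r was 0.812 and rho 0.834, with exact permutation p of 0.05 and 0.04, and other reassignments reached an absolute r of up to 0.882 after the same step. No slide held all 4 groups, so the correlation could not be computed within a slide.

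Offspring and dams kept in filtered air differed at 43 probes, 12 higher and 31 lower in offspring, and 4524 had an unadjusted p under 0.05. The groups did not overlap for 17.2% of probes, where chance gives 10%. Probe A_51_P428708 measured 51.9 ± 31.0% in offspring air and 278 ± 7.63% in dam air (SD, n = 3 each), a log2 difference of -2.58 with a standard error of 0.30 and an adjusted p of 0.0155 in limma. Probe A_52_P378959 measured 4.27 ± 1.09% and 11.7 ± 2.28% in the same order. Higher in offspring were A_51_P259638, at 5.49 ± 1.18% against 2.16 ± 0.246%, and A_52_P118638, at 30.7 ± 4.25% against 14.6 ± 0.922% (SD, n = 3 each). The median correlation between an offspring air and a dam air array was 0.988, and among the offspring air arrays it was 0.987. With slide as a fixed block 0 probes were called and with slide as a random block 43, and a fit of the 2 groups alone called 1. Of the calls, 27.9% were higher in offspring, against 5.6% without scaling, 0% with spike-in scaling and 49.3% with array weights. The count was 1233 without offspring air replicate 1, of which 55.1% were higher in offspring, and 16 without replicate 3. It was 476 without dam air replicate 2 and 0 without dam air replicate 1 or 3. Leaving out a smoke array, which changes only the shared spread, gave 73 and 28 for dam smoke replicates 1 and 2 and 18, 24 and 18 for the offspring smoke arrays. The 4 named probes kept their direction but lost their calls in between 7 and 13 of 27 or 28 alternative settings, each with slide as a fixed block (adjusted p 0.186), where the log2 difference of A_51_P428708 was -2.52; with slide as a random block all 4 stayed called (adjusted p 0.0171 to 0.0246).

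In smoke, offspring and dams differed at 12989 probes, 7042 higher and 5947 lower in offspring, a contrast added after the data had been seen. The higher share was 54.2%, against 63.9% with median centring, 1.0% without scaling and 0.2% with spike-in scaling. Probe A_51_P281568 measured 28.8 ± 0.580% in offspring smoke and 3.34 ± 1.48% in dam smoke (SD, n = 3 each), with an adjusted p of 6.03e-04 in limma and, with the spike-in covariate, a log2 difference of 2.96 in place of 3.23 and an adjusted p of 0.0513. Probe A_52_P1054013 measured 4.61 ± 0.734% and 73.1 ± 44.5% in the same order, and 3.83 ± 1.73% in offspring air and 6.31 ± 2.01% in dam air (SD, n = 3 each). Its dam smoke arrays read 82.2%, 24.8% and 112%, above every dam air array, so this difference lay in dam smoke. Limma did not call it for smoke in dams. Slide as a block left 9169 calls, and the spike-in covariate left 1798.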

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

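The counts over other splits and the covariate test were set before their values were seen; the upper bound of the latter was lowered for a time after its value was seen and then restored. The tests of slides, brightness, the spike-in trend over 9 arrays, the control pairs and the mixtures were chosen after the pattern had been seen. The rule for brightness was made stricter after its value of 0.884 had been seen, to at least 2 bright offspring smoke arrays, which changed its verdict from argued against to open.

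A difference between groups was found in the smoke effect itself, which differed between offspring and dams at 6687 probes. Of 100 splits drawn within both stages, 5 gave as many, the real one included, so this count does not exclude chance, and the highest other split gave 12025. The 4 others that gave as many all kept the real offspring groups and divided only the dams differently, while the 93 splits with other offspring groups called 0. This points to the structure of the offspring arrays and may mean that the count says little about smoke in dams. For smoke against air in dams the real count is 0, so all 10 of 10 splits give as many by construction and the count decides nothing (highest other 1). For the other counts 10 splits are too few for a share under 0.05. As many were called in 1 split for offspring (15000 against 1), in 1 for offspring against dams in air (43 against 2), and in 1 for the same in smoke (12989 against 1).

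A signal in probes outside the comparisons, the spike-ins over the 75th percentile, was higher in offspring smoke than in offspring air by 0.71 on the log2 scale (0.7088). The 3 offspring smoke arrays also stood apart from the other 9. A difference between slides is argued against by r = 0.721 across probes between the within-slide smoke difference and that of other arrays. Overall brightness stays open: offspring smoke replicate 1, as bright as the other groups, lay 0.884 of the way from offspring air to the dimmer pair, but it is 1 array. With the spike-in ratio as a covariate a median of 0.764 of the difference was left over the called probes, and between 0.714 and 0.836 with an array left out. What raised the spike-in ratio stays open as a cause of at least part of the difference. The bounds set before were under 0.25 if it were the cause and over 0.75 for every array left out if not. The shares of 0.749 without offspring smoke replicate 1 and 0.714 without offspring air replicate 2 missed the latter. The ratio alone does not show a low lung RNA signal. Offspring smoke replicate 1 had a 75th percentile of 917 and the highest spike-in signal of the 12 arrays, 3134. In replicates 2 and 3 the 75th percentile was low, at 491 and 549, with spike-in signals of 2073 and 1973. Prenatal smoke, litter and the stage or dissection of these offspring also stay open and were not tested against each other.

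Dam smoke replicate 3 and offspring air replicate 2 lay apart from their groups, at 0.384 and 0.194 of the way to the offspring smoke arrays. Over the 9 other arrays this position rose with the log2 spike-in ratio (Pearson r = 0.770, exact permutation p = 0.0263; Spearman rho = 0.383, exact permutation p = 0.312; adjusted 0.105 and 0.417 over 4 relations), but without these 2 arrays, the most distant ratios, r was -0.0919. Over the 6 dam arrays, dam smoke replicate 3 included, r was 0.926 (exact permutation p = 0.110, adjusted 0.219). The relation over the 9 thus rests on these 2, and what raised their spike-in ratio cannot be told apart from other reasons. Their 75th percentiles, 1019 and 868, lay within the range of the other 7 arrays, 839 to 1164. Their spike-in signals, 2809 and 2805, were the highest of the 9, so their ratios came with a high spike-in signal and not with a low 75th percentile. Because the intensities are not scaled between arrays, this does not exclude a lower amount of lung RNA. The 3 prime to 5 prime ratio of the control pairs was the highest of its group in 0 of 3 pairs for dam smoke replicate 3, which argues against RNA integrity there, and in 2 of 3 for offspring air replicate 2, which leaves it open for that array. A mixture with RNA like that of the offspring smoke arrays needs equal linear shares from probes higher and lower there: the shares were 0.207 and 0.483 in dam smoke replicate 3, a difference of -0.277 where 7 other arrays reach 0.0754, which argues against it. In offspring air replicate 2 they were 0.301 and 0.317, a difference of -0.0157. These medians leave a mixture open for that array, beside RNA integrity, but single probes went both ways. At 4 of the 46 probes with a bright and a dark set, only offspring air replicates 2 and 3 were dark. There replicate 2 read less than such a share of offspring smoke would give, as at A_51_P502798, with 5.32% against 36.0% to 36.9%. At 3 others it was bright, like offspring smoke, and the other offspring air arrays were dark.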

How the results depend on the processing

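Settings without floor, without scaling, with spike-in scaling or covariate, and without both arrays that stood apart were chosen after seeing the data; the cause of a change was not tested unless given. For smoke in dams (0) the count was 1036 with array weights, whose estimation stopped before convergence, 6 without scaling, 3 with spike-in scaling, 2 without both arrays, and 0 to 7 without 1 array; all other settings gave 0. For smoke in offspring (15000) it was 9084 with the plain test, 9449 without the dimmer probes, where fewer were tested, 9885 with spike-in scaling, 6982 with the spike-in covariate, and 12483 to 15221 without 1 array. The difference of the effects (6687) gave 42 with slide as a fixed block but 6164 with slide as a random block, 14585 with array weights, 4215 without floor, 10 with spike-in scaling, 10833 without both arrays, 3414 with the covariate, and 3074 to 8920 without 1 array. Offspring against dams in air (43) gave 0 with slide as a fixed block but 43 with slide as a random block, 1 with the 2 groups alone, 1 with the plain test, 145 with a trended robust spread, 2844 with array weights, 65 without the dimmer probes, 9405 over both treatments (6 arrays against 6), 0 without floor, 18 without scaling, 150 with spike-in scaling, 76 without both arrays, 91 with the covariate, and 0 to 1233 without 1 array. Offspring against dams in smoke (12989) gave 1798 with the covariate and 9456 to 13972 without 1 array. The correlation of effects (0.328) was 0.812 with slide means removed, a step that can itself build such a correlation. It was -0.0397 without both arrays, and -0.0557 to 0.480 without 1 array. Where an array was left out, the pair left was assumed to vary like the other groups.

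Arrays of the same number share only a number: within a stage their deviations correlated between -0.164 and 0.218. With the replicate number as a block the counts were 0 for dams, 14169 for offspring, 4449 for the difference of effects, 0 for offspring against dams in air and 12009 in smoke. Of the values of named probes under other settings, 462 kept their side of the threshold, 50 lost it, 9 gained it and 0 changed sign. Tests per probe and with missing values kept are identical to the fit given, and the gene list alternatives were not run. Probes near the floor, at 1.16% of the 75th percentile, carry little signal over background; what size of difference could be detected there was not tested.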

Other observations

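The tests of distances and of all-or-none probes were chosen after the patterns had been seen; the counts of 43 and 1233 probes come from planned settings.

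Offspring air and dam air arrays differed at 43 probes, which may be few if the offspring lungs were taken before birth. Root mean square distances between an offspring air and a dam array ran from 0.382 to 0.615 log2 units, and between dam arrays from 0.258 to 0.450. Of the 18 distances, 5 lay within the range between dams, 4 of them of offspring air replicate 1, 1 of replicate 3 and 0 of replicate 2, and without replicate 1 the count of probes was 1233 in place of 43. Whether the arrays labelled offspring air hold lung RNA of adult mice cannot be told apart from a small difference between the stages. The age of the offspring at collection is not among the sample details used here, so offspring sampled at a later age also stay open.

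At 356 of 41174 probes the arrays fell into a bright and a dark set more than 4-fold apart, with a gap wider than the spread inside either set. Of these, 310 were bright on 1 array alone, between 13 and 45 per array. Of the 46 others, 35 split the offspring air arrays, 9 the dam smoke, 7 the offspring smoke and 4 the dam air arrays. Probes A_51_P508781, A_52_P570717, A_52_P152133 and A_51_P281568, named in the comparisons above, are among the 46. Independent spot artefacts are argued against by 7 probes bright on exactly offspring air replicates 2 and 3, where the single-array numbers give 0.0134. Both arrays were on slide 3, where dam smoke replicate 3 and dam air replicate 3 were dark at these probes. A fault shared by the 2 offspring air arrays alone was not tested. Whether offspring air replicate 1 holds RNA of a mouse like the 6 dams stays open: 5 probes were bright on exactly that array and the 6 dams, whereas 8 probes were dark on that array alone, against at most 3 on any other. Inherited differences between offspring may leave such a pattern and were not tested; per the labels every mouse was female and of 1 strain, written B6C6F1, and neither was checked here.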
